A study of Bifidobacterium breve UCC2003 with 12 samples.

How the data were processed

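Total RNA of Bifidobacterium breve UCC2003 was hybridised to 2-colour Agilent oligonucleotide arrays, 1 test RNA and 1 reference RNA per array in Cy3 and Cy5. Per the labels, cultures grew without oxygen in CDM medium for the starvation arrays and in MRS medium for the overexpression arrays, and the 12 arrays fall into 6 groups, 3 groups of 3 arrays and 3 single arrays. The test RNA was in Cy5 on 7 arrays and in Cy3 on 5. The 3 arrays at 45 min had the test RNA in Cy5, the 3 overexpression arrays had it in Cy3, and at 90 min array 1 had it in Cy5 and arrays 2 and 3 in Cy3.

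The deposited scanner files hold a spot's mean intensity and the median intensity of its local background in each dye, quantified with Agilent Feature Extraction, per the file headers, with no further normalization. The headers name version 9.5.1.1 for 7 arrays, with 9.1.3.1 for 90 min arrays 1 and 2 and 9.1.1.1 for the mutant arrays, where the submitters' processing notes name version 9.5. The deposited files also give processed intensities, which Feature Extraction had background-subtracted, detrended and dye-normalized, and their log10 ratio of Cy5 over Cy3, per the file headers. A deposited value table gives 1 log10 ratio per spot. Set against the scanner files spot by spot, it held that log10 ratio unchanged on the arrays with the test RNA in Cy5 and with its sign turned on the 5 arrays with it in Cy3 (largest difference 4.996e-06), so it gives test over reference throughout, uncentred. Its medians per array lay between -0.02498 and 0.01007 on the log10 scale.

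Each array held 10263 spots for genes among 10807, representing 5664 probes of 60 bases, 3 for each of 1888 features, of which 4599 probes were spotted 2 times and 1065 once. The features comprised 1843 with a locus tag, 20 tRNA features, 15 named after plasmids, 3 with other names and 7 spike-in controls. The spike-in controls were left out. Median signals ran from 87.5 (Cy3 of overexpression array 1) to 2690 (Cy5 of overexpression array 2), over median local backgrounds of 33 to 61. Spots with outlier marks were left out. They made up 16.9% of spots on the mutant array starved for 90 min, 36.9% and 52.7% on the arrays of mutant over wild type at 45 and 90 min, and at most 17 spots on any other array. Saturated spots were kept, and were most frequent in Cy5 of 45 min array 1 (253) and of overexpression arrays 2 and 3 (190 and 166).

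Signals were background-corrected with the normexp method (offset 50) and normalized by loess within each array with control spots at weight 0, in limma. Log2 ratios were turned to test over reference by the dyes in the labels, spots of a probe were averaged, and a feature took the median of its 3 probes. Features were tested if a probe was well above background in a channel on at least 3 of the 12 arrays, which left 1875. Of the plasmid-named features 10 were tested. Log2 ratios were fitted with limma's lmFit, with 1 coefficient per group over all 12 arrays, and eBayes, leaving 6 residual degrees of freedom and 2.67 prior degrees of freedom. A feature passed at a Benjamini-Hochberg adjusted p under 0.05. Ratios were tested against 0 at 45 min, at 90 min and on overexpression. The difference of 90 and 45 min, and of the mutant's and the wild type's 90 min response, were contrasts of the same fit. Single mutant arrays were described by their ratios and 2-fold counts, and lists of features on them by the percentile of their median among 10000 random lists of the same size matched on mean signal. Random lists draw features singly and do not keep runs of neighbouring tags, so percentiles near 0 or 100 may be too extreme. Overlaps used Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. The share of features with a changed neighbouring tag was set against 1000 random draws of as many tags. That count, and the overlaps with the mutant arrays, were chosen after the data were seen.

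Before the data were examined, 20 gene lists (phosphate uptake, phosphate scavenging, PhoRP, ribosomal proteins and other functions) were fixed by gene symbol and product. The files name most features by locus tag and none by the symbols of these lists, and the reference table (2016 genes of another strain) matched 0 features, so these lists hold 0 measured features and were not run. Features named in the comparisons followed a rule written before the data were examined, as those with the largest rises and falls among features that passed with 1 direction on all arrays of a group. For the single mutant arrays the rule took the highest and lowest ratios among features well above background. Because tags have no names here, 2 each way are printed per comparison. The runs led by Bbr_1310 and Bbr_1879, and the single tRNA and plasmid-named features, were chosen after their values were seen. The tRNA features and the features named after plasmids were added as groups after the data were seen, and tested with limma's camera (preset correlation), camera with an estimated correlation, and fry, on the 9 replicated arrays.

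Arrays were grouped into 7 slides from the file headers, and the scan sessions followed the slides. The labels' replicate numbers were checked as pairs by correlating deviations from the group means. Alternatives fixed before the data were examined were no background correction, offset 16, Agilent's processed signals, median centring, Aquantile, no filter or a filter on at least 9 arrays, the mean of probes, the deposited value table, a dye coefficient per feature, slide as a random block, a trended and robust variance, the compared arrays alone, an added 2-fold minimum, the replicate number as a block, and leaving out each array. Keeping spots with outlier marks, averaging the arrays of 1 slide and group, and slide within each group as a random block were added after the data were seen.

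The fits were tested on simulated data of 1875 features, with 200 changed, 50 at each of 1.5-fold, 2-fold, 4-fold and 8-fold. With independent noise, the 90 min test recovered 26, 38, 49 and 48 of them by size and passed 11 of 1675 unchanged features. With noise shared within slides (correlation 0.9) it passed 108 unchanged features at 90 min, and 28 with slide as a random block. The corresponding counts of unchanged features were 7, 111 and 7 at 45 min, 8, 105 and 24 on overexpression, 8, 105 and 6 for the difference of times, and 5, 65 and 5 for the mutant's difference from the wild type. The tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.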

Results

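DNA microarrays measured transcript levels in Bifidobacterium breve UCC2003, a bacterium of the infant gut, during phosphate starvation and in strains with altered phoP. The gene phoP encodes the response regulator of PhoRP, a signalling pair in which a sensor kinase passes a signal to a regulator of transcription. Each of the 12 arrays compared 2 RNA samples carrying different dyes, so every value is a ratio of test RNA over reference RNA. Wild-type cells starved for 45 min or for 90 min were compared with wild-type cells at normal phosphate, on 3 arrays per time. A strain overexpressing phoP from a plasmid was compared with the wild type in MRS medium, on 3 arrays. The phoP mutant was measured on 3 single arrays: mutant starved for 90 min over mutant at normal phosphate, mutant over wild type with both starved for 45 min, and mutant over wild type with both starved for 90 min. The number of arrays limits the precision of every comparison, and values from the single arrays have no replicate error.

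Each array held 10263 spots for genes, and between 69.4% and 99.2% of them were well above background in a channel, with the lowest share in the Cy5 channel of 45 min array 2. Replicate arrays were alike mainly where they shared a slide. The 90 min arrays 1 and 2 lay on 1 slide and correlated at r = 0.995 across features, against 0.691 and 0.692 with array 3 on another slide. Taken per array, as the SD of their differences over the square root of 2, the spread between probe ratios of arrays 1 and 2 was 0.08 on the log2 scale. Computed the same way, the spread between duplicate spots within each of them was 0.05 and 0.06. Most probe ratios average 2 spots, so these values are not like for like. Overexpression arrays 2 and 3 shared a slide with r = 0.976, while array 1 correlated with them at 0.361 and 0.392. Array 1 of the 45 min group correlated with arrays 2 and 3 of its group at 0.395 and 0.333, and with the 3 arrays of the 90 min group at 0.758, 0.752 and 0.751. These correlations run across features, which are not independent replicates. The labels do not say which arrays came from separate cultures, so p-values measure the spread between arrays, part of which may be technical. At 90 min and on overexpression the 2 arrays of 1 slide were nearly copies, so n = 3 overstates the replicates. Where noise is shared within slides, the limma p-values are too small. In simulated data with such noise the 90 min test passed 108 unchanged features, against 11 with independent noise. Beside each count of changed features, the count with the arrays of 1 slide averaged as 1 replicate is therefore given.

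**Figure D1:**
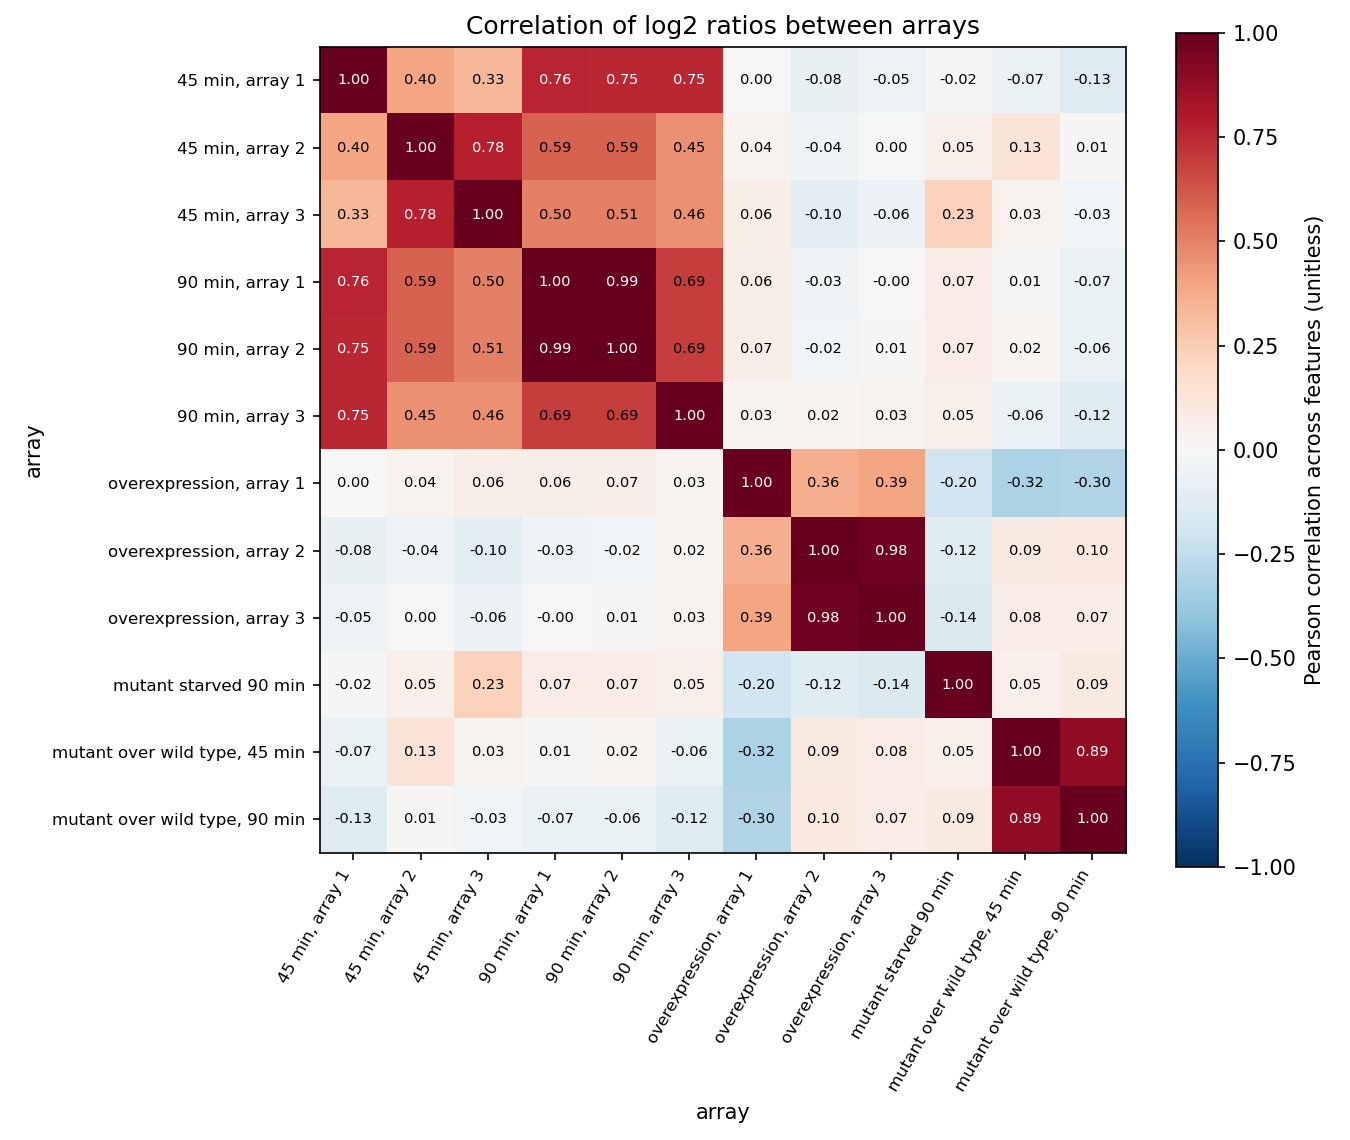
Pearson correlation (unitless, colour scale from -1 to 1) of log2 ratios across features for each pair of the 12 arrays, with arrays on both axes. Arrays of 1 group on the same slide reach 0.775 (45 min arrays 2 and 3), 0.995 (90 min arrays 1 and 2) and 0.976 (overexpression arrays 2 and 3), and the mutant array starved for 90 min lies near 0 against the wild-type starvation arrays apart from 0.229 with 45 min array 3.

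Most features carry locus tags of strain UCC2003, and the files do not pair these tags with gene names. The reference table at hand is of another strain and matched 0 of the 1888 features, so phoP, phoR and the phosphate uptake genes are not named here, and the level of phoP in the mutant and the overexpressing strain was not checked. In the comparisons below at most 2 features that rose and 2 that fell are named for each, with the runs of consecutive locus tags they belong to.

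The first question was how the wild type responded after 45 min without phosphate. Bbr_1682 rose furthest, with a mean log2 ratio of 3.45 ± 1.13 (SD, n = 3; limma adjusted p = 0.00154). Its neighbour Bbr_1681 rose 5.84-fold, with a log2 ratio of 2.55 ± 0.47 (SD, n = 3; limma adjusted p = 0.00114). Both lay in a run of 6 consecutive tags that all rose, with a median log2 ratio of 1.85. The largest falls were those of Bbr_1419, which fell by 1.72 ± 1.18 on the log2 scale (SD, n = 3; limma adjusted p = 0.0196), and of Bbr_0384, which fell by 1.64 ± 1.56 (SD, n = 3; limma adjusted p = 0.0361). Bbr_0384 fell by 3.42 on array 1 and by 0.50 and 1.00 on arrays 2 and 3. Both falls depend on single arrays and on the fit. Bbr_1419 did not pass without array 1 (-1.34, adjusted p = 0.0768) or without array 3 (-1.41, adjusted p = 0.101). Bbr_0384 did not pass without array 3 (-1.96, adjusted p = 0.068), without background correction or with a trended and robust variance, and stood at -0.75 without array 1. Neither passed with a dye coefficient (-1.85 and -1.51), with slide as a random block (-1.89 and -2.06), with the arrays of 1 slide averaged (-1.90 and -2.09) or with the 45 min arrays alone, so these calls ended without smaller changes, apart from the dye coefficient for Bbr_0384.

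Across all features at 45 min, 353 of 1875 passed the limma test, 206 higher and 147 lower, and 352 of them had 1 direction on all 3 arrays. Of these, 92 changed at least 2-fold, 64 upwards and 28 downwards. The changes were grouped along the genome. Of 204 risen features with a locus tag, 112 had a risen feature as a neighbouring tag, against a mean of 41.3 and a highest value of 65 in 1000 random draws. Of the 147 fallen features, 73 had a fallen neighbour, against a mean of 21.7 and a highest value of 44. Risen features formed 18 runs of at least 3 tags, the longest of 8, and fallen features formed 13, the longest of 7. With the arrays of 1 slide averaged limma passed 0 features at 45 min (369 at an unadjusted p under 0.05), with the 45 min arrays fitted alone 0 (462 unadjusted), with slide as a random block 0 (305 unadjusted) or 33 when taken within each group, and with a dye coefficient 13. Leaving out array 2 gave 217 features, leaving out array 3 gave 177, and with the arrays of 1 slide averaged Bbr_1682 and Bbr_1681 both had an adjusted p of 0.0847, at log2 ratios of 3.13 and 2.42. Both also missed the threshold with slide as a random block (adjusted p = 0.0504, at 3.15 and 2.42) and with the 45 min arrays alone (adjusted p = 0.0554), as did Bbr_1682 with a dye coefficient (adjusted p = 0.0524, at 3.72).

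After 90 min without phosphate the largest rises were again those of the neighbours Bbr_1682 and Bbr_1681. Bbr_1682 rose 26.1-fold, with a mean log2 ratio of 4.71 ± 0.48 (SD, n = 3; limma adjusted p = 0.00015), and Bbr_1681 rose 14.1-fold, with 3.82 ± 0.23 (SD, n = 3; limma adjusted p = 9.13e-05). They belonged to a run of 8 consecutive risen tags with a median log2 ratio of 2.72. A second run of 9 risen tags, which holds Bbr_0327 and Bbr_0329 (named for the comparison of times), had a median of 2.89. Bbr_1431 fell by 3.03 ± 0.82 on the log2 scale (SD, n = 3; limma adjusted p = 0.00473) and led a run of 11 consecutive fallen tags with a median of -1.79. Bbr_1003 fell by 2.73 ± 0.36 (SD, n = 3; limma adjusted p = 0.00121).

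**Figure D2:**
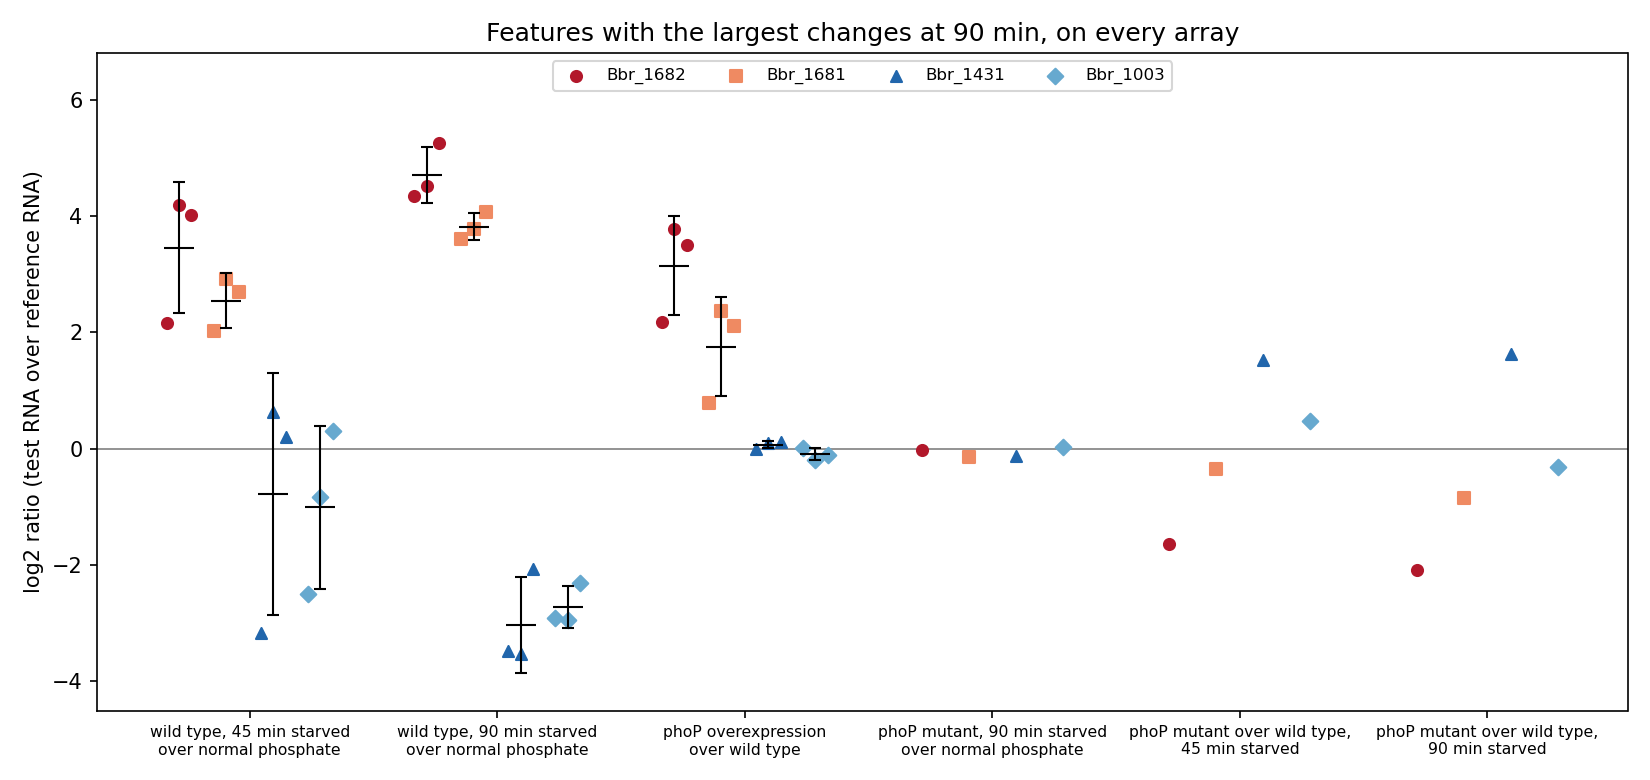
Log2 ratio of test over reference RNA (y axis) on every array of the 6 groups (x axis) for the features with the largest changes at 90 min. Each point is 1 array, and bars show mean ± SD where a group has 3 arrays. Bbr_1682 has a mean of 3.45 at 45 min, 4.71 at 90 min and 3.15 on overexpression, against -0.03 on the mutant array starved for 90 min, and Bbr_1431 spreads widely at 45 min, where array 1 alone is strongly negative (-3.17).

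In all, 955 of 1875 features passed the limma test at 90 min, 477 higher and 478 lower, which is 50.9% of those tested. All 3 arrays had 1 direction for 917 of them. Changes of at least 2-fold were seen for 357, of which 161 rose and 196 fell. Of 474 risen features with a locus tag, 334 had a risen neighbour, against a mean of 205 and a highest value of 249 in 1000 random draws, and 360 of 478 fallen features had a fallen neighbour, against a mean of 209 and a highest value of 252. Risen features formed 51 runs of at least 3 tags and fallen features 56. With the arrays of 1 slide averaged, 216 features passed, 112 higher and 104 lower, and slide as a random block gave 370, or 343 when taken within each group. Leaving out array 1 gave 511 features and leaving out array 2 gave 496, and Bbr_1431 had an adjusted p of 0.0697 with the arrays of 1 slide averaged, at a log2 ratio of -2.79, whereas Bbr_1682, Bbr_1681 and Bbr_1003 passed under every alternative that was run, with adjusted p of at most 0.0136, 0.0122 and 0.0378.

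The responses at 45 and 90 min overlapped. Of the 206 features higher at 45 min, 175 were also higher at 90 min, where independent lists would share 52.4 (Fisher's exact test, two-sided, p = 6.24e-83, adjusted over the 14 overlaps computed to 8.74e-82). Of the 147 lower features, 109 were also lower at 90 min, against 37.5 for independent lists (Fisher's exact p = 2.36e-38, adjusted 1.65e-37). Fisher's test takes features as independent, although neighbouring tags moved together, so these p-values are too small. Opposite calls were rare, with 3 features higher at 45 min and lower at 90 min and 0 the other way round. With the arrays of 1 slide averaged both overlaps were 0, since 0 features then passed at 45 min. Array 1 of the 45 min group correlated at 0.751 to 0.758 with the 90 min arrays, against 0.395 and 0.333 with its own group. The overlaps were not computed without that array, which may supply part of them.

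Whether the response itself changed between 45 and 90 min was tested as a difference of log2 ratios. Bbr_0327 stood at 2.89 ± 0.24 at 90 min and 1.12 ± 0.48 at 45 min (SD, n = 3 each), a difference of 1.76 (limma adjusted p = 0.0214). Bbr_0329, from the same run, stood at 2.83 ± 0.10 and 1.15 ± 0.16, a difference of 1.68 (limma adjusted p = 0.00163). Bbr_0182 was higher than at normal phosphate at 45 min (1.57 ± 0.71) and lower at 90 min (-1.30 ± 0.22), a difference of -2.87 (limma adjusted p = 0.00573). Bbr_0925 went from 0.14 ± 0.57 to -2.19 ± 0.24, a difference of -2.33 (limma adjusted p = 0.0169). In all 6 features passed, 3 with a higher ratio at 90 min, which were consecutive tags, and 3 with a lower one, and 377 had an unadjusted p under 0.05. The count was 0 with a dye coefficient (247 unadjusted), with slide as a random block (68, or 60 within each group) and with the arrays of 1 slide averaged (45), and 2 with the 45 and 90 min arrays alone. The 68, 60 and 45 are fewer than the share of 0.05 of features expected with no change. The count was 452 without 45 min array 1 and 419 without 90 min array 3, and the dye orientation was not balanced over the times. Leaving out either array leaves only arrays of 1 slide in its group, whose spread may be largely technical. Those 2 counts therefore do not show that the array left out hid changes. With median centring 7 features passed, 3 of them shared with the 6, and the differences of Bbr_0327 and Bbr_0329 were 1.11 (adjusted p = 0.0926) and 1.18 (adjusted p = 0.0765). Bbr_0327 and Bbr_0925 also did not pass without 45 min array 2 (adjusted p = 0.0931 and 0.0907), without 90 min array 1 (0.13 and 0.0589) or without 90 min array 2 (0.0748 each).

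Overexpression of phoP was compared with the wild type to find the features that respond to more PhoP without starvation. Bbr_1683 was 146-fold higher in the overexpressing strain, with a mean log2 ratio of 7.19 ± 0.78 (SD, n = 3; limma adjusted p = 1.39e-06). Bbr_1682, the feature with the largest rise under starvation, was 8.85-fold higher, with 3.15 ± 0.85 (SD, n = 3; limma adjusted p = 0.0146). With their neighbours they made up the 4 features that rose, the consecutive tags Bbr_1681 to Bbr_1684. Bbr_0890 was lower by a log2 ratio of -2.00 ± 0.24 (SD, n = 3; limma adjusted p = 0.026) and lay in a run of 3 consecutive fallen tags. Bbr_1893 was at -1.76 ± 0.42 (SD, n = 3; limma adjusted p = 0.00585).

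In all 12 of 1875 features passed on overexpression, 4 higher and 8 lower, each with 1 direction on all 3 arrays, and 209 had an unadjusted p under 0.05. All 4 features that rose were also higher at 90 min of starvation, where independent lists would share 1.02 (Fisher's exact p = 0.00415, adjusted 0.0116). These 4 are neighbouring tags of 1 run, which Fisher's test counts as independent, so its p-value is too small for what amounts to 1 locus. That overlap was 1 feature with a dye coefficient (Fisher's exact p = 0.232) and 1 with the arrays of 1 slide averaged (0.0597), and the 477 features higher at 90 min had a median of -0.05 on overexpression, at percentile 0 of the random lists. The median is small, and the random lists do not keep runs of neighbouring tags, so that percentile may be too extreme. Of the 8 that fell, 2 were lower at 90 min, against 2.04 for independent lists (Fisher's exact p = 1), and 4 were higher there, against 2.03 (Fisher's exact p = 0.12, adjusted 0.21). With the arrays of 1 slide averaged only Bbr_1683 passed (limma, 41 features unadjusted), and 1 feature passed with a dye coefficient, 2 with slide as a random block or 1 within each group, and 495 with median centring in place of loess, 396 higher and 99 lower. The 41 are fewer than the share of 0.05 of features expected with no change. Leaving out array 1 gave 111 features, of which 92 were higher, leaving out array 2 gave 1 and leaving out array 3 gave 4. Without array 1 only arrays 2 and 3 stay, near copies on 1 slide, so the 111 may rest on technical spread. Bbr_1683 passed under every alternative that was run, with adjusted p of at most 0.0484, and Bbr_1682 did not pass in the fits with a dye coefficient, with slide in the model or averaged, with the overexpression arrays alone, or without array 2 or 3. Bbr_0890 and Bbr_1893 did not pass with a dye coefficient, with slide in the model or averaged, or without array 2.

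In the phoP mutant, the features that led the wild-type response were near a ratio of 1 after 90 min of starvation. On the mutant's single starvation array, Bbr_1682 had a log2 ratio of -0.03 and Bbr_1681 of -0.15, against 4.71 and 3.82 in the wild type. The mutant has no replicate here, so the test of a difference takes its spread from the other groups, and a pass does not separate an effect of the mutation from variation of 1 array. By that test the differences from the wild-type response were -4.74 for Bbr_1682 (limma adjusted p = 0.0259) and -3.97 for Bbr_1681 (limma adjusted p = 0.0221). Among features that fell in the wild type, Bbr_0750 stood at 0.79 in the mutant against -2.07 ± 0.05 in the wild type (SD, n = 3), a difference of 2.86 (limma adjusted p = 0.0354), and Bbr_0720 at 0.01 against -2.67 ± 0.75, a difference of 2.68 (limma adjusted p = 0.0301). The run of 9 tags with Bbr_0327 was not flat on the mutant array, with a median of 0.97 against 2.89 in the wild type.

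The difference between the mutant's and the wild type's 90 min response passed the limma test for 88 of 1868 features, 44 higher and 44 lower in the mutant, with 544 at an unadjusted p under 0.05. This test sets 1 mutant array against 3 wild-type arrays and assumes that the single array varies like the other groups, whose replicates partly share slides, so the count is no measure of how many features need phoP. Of the 161 features that rose at least 2-fold in the wild type, 11 rose at least 2-fold on the mutant array, out of 20 such features in all. The 161 had a median of 0.03 there, at percentile 73.3 of 10000 random lists of the same size and mean signal. Most of the array's 2-fold rises were therefore wild-type rises, while the list as a whole stood near 0. Of the 196 that fell at least 2-fold, 1 did so on the mutant array, with a median of 0.04 at percentile 88.7. Over all features, 20 were at least 2-fold higher and 10 at least 2-fold lower on the mutant array, led upwards by Bbr_0579 (2.24) and Bbr_0876 (2.21) and downwards by Bbr_0013 (-1.92) and Bbr_0033 (-1.55). With a dye coefficient 15 were higher and 17 lower. The count of 88 was 0 with a dye coefficient (443 unadjusted), with slide as a random block (222, or 267 within each group), with the arrays of 1 slide averaged (256) and with the compared arrays alone (490), and 4 with a trended and robust variance. Leaving out wild-type array 1, 2 or 3 gave 4, 5 or 549 features, and none of the 4 named features passed without array 1 or without array 2. Without array 3 the wild type rests on arrays 1 and 2, near copies on 1 slide, so the 549 may rest on technical spread.

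**Figure D3:**
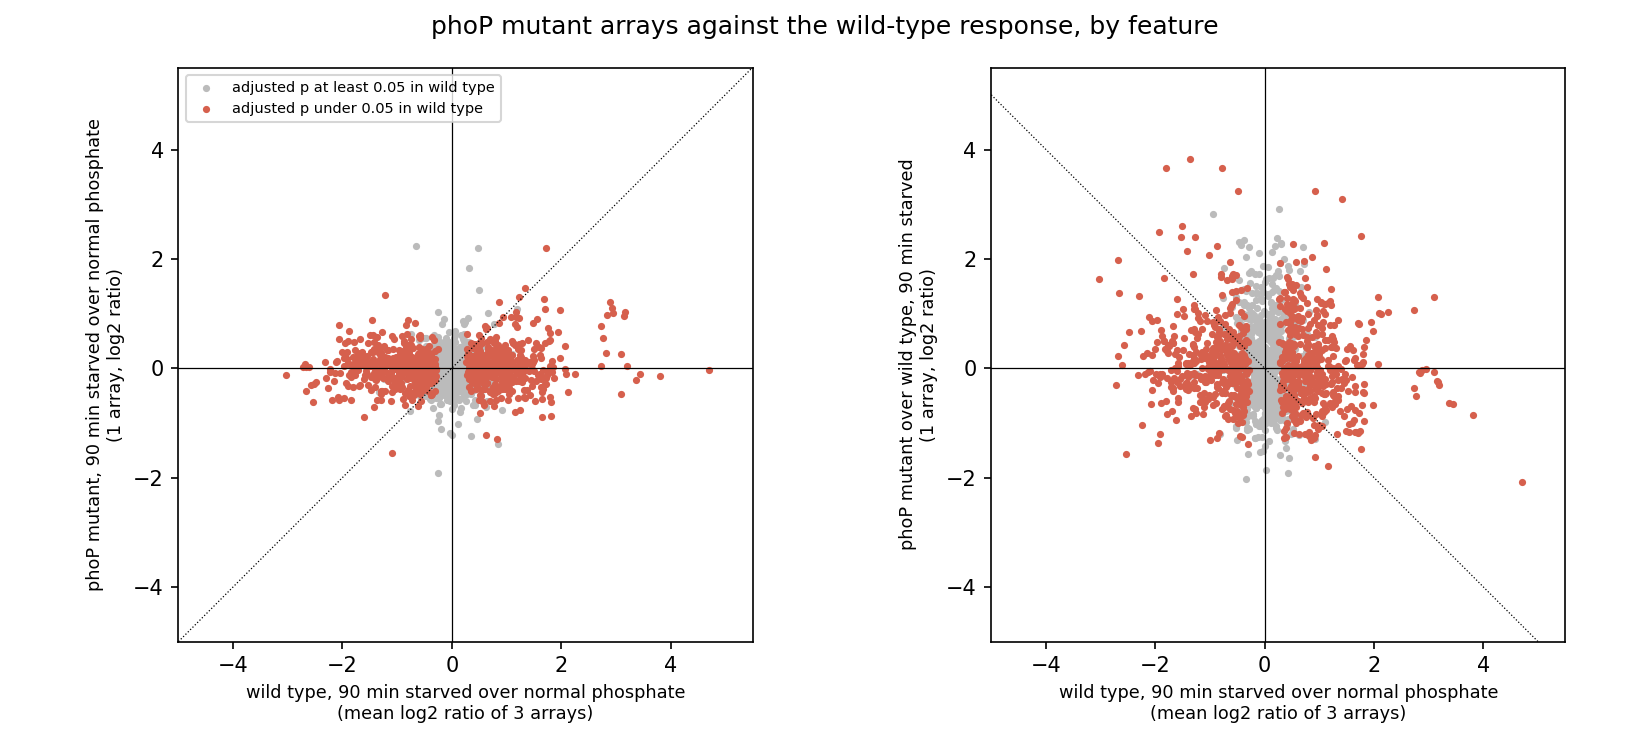
Log2 ratios of the single phoP mutant arrays (y axis) against the mean log2 ratio of the 3 wild-type arrays at 90 min (x axis), 1 point per feature, with features that passed the wild-type test in red. On the left, mutant starved over mutant at normal phosphate stays close to 0 (r = 0.07 across features; dotted line, equal response); on the right, mutant over wild type, both starved, has r = -0.08 (dotted line, the value if the mutant had the wild type's starting levels and did not respond).

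Mutant and wild type were also compared directly under starvation, on 1 array at 45 min and 1 at 90 min. Bbr_1893 was saturated in the mutant channel on both arrays, so its log2 ratios of 3.94 at 45 min and 3.83 at 90 min are lower bounds. The same holds for Bbr_1892, with at least 3.72 at 45 min and at least 3.66 at 90 min. Bbr_1893 led a run of 5 consecutive tags with medians of at least 3.72 at 45 min and of 3.66 at 90 min, which stood at a median of -1.59 on overexpression. Bbr_0305 stood at 4.39 at 45 min, from the 1 probe left without outlier marks, and its rank against the saturated features is not known. On the low side, Bbr_1289 and Bbr_1290 stood at -2.30 and -2.24 at 45 min, in a run of 4 tags with medians of -2.21 and -1.53 at the times. Bbr_1682 was lowest at 90 min, with -2.08, followed by Bbr_1658 with -2.03. The run of 6 tags around Bbr_1682 that rose in the wild type moved less here. Its medians were -0.46 at 45 min and -0.64 at 90 min, with members up to 0.20 and 0.15.

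Of 1702 features with a value on both arrays, 141 were at least 2-fold higher and 39 at least 2-fold lower in the mutant at both times, and 0 were 2-fold apart in opposite directions (r = 0.886 across features). These arrays shared a slide, and outlier marks removed 36.9% and 52.7% of their spots. The 146 features that rose at least 2-fold in wild-type starvation and had a value had a median of -0.10 at 90 min, lower than most random lists (percentile 0.71) but small beside their own rise of 1.40, and 64 of them were above 0. On the 45 min array this list had a median of 0.01 (percentile 75.5). The features that fell at least 2-fold had medians of 0.10 at 90 min (percentile 59.5) and -0.14 at 45 min (percentile 0.96). Since the random lists do not keep runs of neighbouring tags, the percentiles of 0.71 and 0.96 may be too extreme. Of the features higher at 90 min in the wild type, 13 were at least 2-fold lower in the mutant on both arrays, against 9.88 for independent lists (Fisher's exact p = 0.264, adjusted 0.364). Bbr_1682 was the only feature higher at 90 min, higher on overexpression and at least 2-fold lower in the mutant on both arrays. Bbr_1892 and Bbr_1893 were the only ones lower at 90 min, lower on overexpression and at least 2-fold higher in the mutant on both arrays. The overlap of falls on overexpression with rises in the mutant, those 2 features, was larger than the 0.663 of independent lists but did not pass the test (Fisher's exact p = 0.137, adjusted 0.213).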

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

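Of the tests in this part, those of dim signal and of the starting level for the mutant array, of slide or culture for 45 min array 1, and the splits of the samples were chosen only after the result was seen.

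The wild-type response differed between 45 and 90 min for 6 features by limma's test of the difference. The named ones were Bbr_0327 and Bbr_0329, whose log2 ratios were higher at 90 min by 1.76 and 1.68, and Bbr_0182 and Bbr_0925, whose ratios differed by -2.87 and -2.33. Splitting the 6 wild-type arrays into 3 and 3 in every way gave 10 splits, too few for a share under 0.05. The real split gave 6 features, 2 of the 10 splits gave as many (the real one included), and the highest other gave 374. That split put 45 min array 1 with 90 min arrays 1 and 2 against the rest. Like the real split, it kept arrays of 1 slide together. All the other splits parted arrays of 1 slide, which widens the spread within groups, so their low counts are no measure of chance. The split with 374 points to differences between arrays that do not follow the time of starvation. With slide as a random block 0 features passed limma's test (68 unadjusted), and 452 passed without 45 min array 1 and 419 without 90 min array 3. The 68 are fewer than the share of 0.05 expected with no change. The fits with an array left out leave only arrays of 1 slide in a group, whose spread may be largely technical.

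For 88 features the response at 90 min of the phoP mutant, on 1 array assumed to vary like the other groups, passed limma's test of the difference from the wild type, which cannot separate the mutation from variation of that array. The named ones had differences of 2.86 for Bbr_0750, 2.68 for Bbr_0720, -4.74 for Bbr_1682 and -3.97 for Bbr_1681. Without 90 min arrays 1, 2 and 3 in turn the count was 4, 5 and 549, the last with only the near copies on 1 slide left. It was 0 with a dye coefficient (443 unadjusted), with slide as a random block (222), with the arrays of 1 slide averaged (256) and with the compared arrays alone (490).

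Array 1 of the 45 min group stood apart from arrays 2 and 3 of its group. Dim signal is argued against as the whole cause, since the correlation of array 1 with array 3 was 0.325 across the 469 brightest features and 0.333 across all, and that with array 2, the dimmest, was 0.461 and 0.395, against 0.759 between arrays 2 and 3 across the brightest. On a scale where 0 is the level of 45 min arrays 2 and 3 and 1 is the 90 min mean, array 1 had a median position of 0.972 (quartiles 0.64 and 1.30) over 452 features, and 382 of these lay nearer 90 min. That is consistent with 90 min RNA on array 1, and a departure of arrays 2 and 3, which share a slide, would look the same. A slide effect and a difference between cultures cannot be told apart here, because array 1 is alone on its slide, and a faster response of 1 culture stays open as well.

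The mutant array starved for 90 min was nearly flat, and dim signal is argued against as the cause, since its dimmer channel had a median 3.17 times the highest channel median of the wild-type 90 min arrays (1271 against 400.3). Removal of changed spots by outlier marks is argued against too, since with all spots kept the SD of its log2 ratios was 0.325, against at least 0.71 on the wild-type arrays. A mutant that began at the wild type's levels and changed only as its own starvation array shows would put the 146 features that rose at least 2-fold in the wild type at a median of -1.34 (quartiles -1.83 and -1.05) on the array of mutant over wild type at 90 min, where they had -0.10 (quartiles -0.56 and 0.41). For the arrays to fit together, these features would have to start higher in the mutant at normal phosphate, by a median over single features of 1.33 on the log2 scale. Such a raised starting level, a label that differs from the RNA on 1 of these single arrays, and a difference between cultures may each account for this, and were not tested.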

How the results depend on the processing

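Keeping spots with outlier marks, averaging the arrays of 1 slide and group, slide within each group as a random block, and the tests of the tRNA and plasmid-named groups were chosen only after the result was seen. Counts are of features passing limma's test, given in the order 45 min, 90 min, 90 minus 45 min, overexpression and mutant minus wild type where several are listed, beside 353, 955, 6, 12 and 88 as reported. The cause of a changed count was not tested, except that fewer replicates enter where arrays are left out or averaged.

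With an added 2-fold minimum 92 and 357 passed at 45 and 90 min. Without background correction 157 passed at 45 min (110 higher and 47 lower, 70.1% higher against 58.4%) and 174 for the mutant. Agilent's processed signals gave 11 for 90 minus 45 min and 47 on overexpression (68.1% higher against 33.3%), and the deposited value table gave 14 and 40 (67.5% higher). These settings gave 39.0% and 39.6% higher for the mutant against 50%. Median centring gave 214 at 45 min, 495 on overexpression (80% higher) and, for the mutant, 74 with 74.3% higher. A dye coefficient gave 13 at 45 min, 0 for 90 minus 45 min, 1 on overexpression and 0 for the mutant. It is estimated from the 90 min arrays alone, where it also takes in how array 3 differs. These lower counts therefore do not measure dye effects in the other groups. Slide as a random block (correlation 0.916) gave 0, 370, 0, 2 and 0, slide within each group (0.909) gave 33, 343, 0, 1 and 0, and averaging the arrays of 1 slide gave 0, 216, 0, 1 and 0. A trended and robust variance gave 3 for 90 minus 45 min and 4 for the mutant. The compared arrays alone gave 0 at 45 min, 2 for 90 minus 45 min, 3 on overexpression and 0 for the mutant. For the counts of 0, unadjusted p under 0.05 was reached by between 45 features (90 minus 45 min, averaged) and 490 (mutant, compared arrays alone). A share of 0.05 of the features tested is expected there with no change. The counts for 90 minus 45 min with slide as a random block or averaged lie below it.

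Leaving out 1 array at a time gave between 177 and 428 features at 45 min, 496 and 1030 at 90 min, 4 and 452 for 90 minus 45 min, 1 and 111 on overexpression, and 4 and 549 for the mutant. The low values came without 45 min array 3, without 90 min array 2, and without overexpression array 2, and the high ones for 90 minus 45 min and overexpression without array 1 of the 45 min and the overexpression group. For the mutant the lowest count came without 90 min array 1 and the highest without 90 min array 3. Without 90 min array 3, or without array 1 of the 45 min or the overexpression group, only arrays of 1 slide stay in that group. They are near copies at 90 min and on overexpression, so their spread may be largely technical. The higher counts then do not show that the array left out hid changes.

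With the replicate number as a block the counts were 71 at 45 min, 687 at 90 min, 0 for 90 minus 45 min (302 unadjusted) and 9 on overexpression, and with a dye coefficient as well 0 at 45 min (335 unadjusted), 684 at 90 min and 0 for 90 minus 45 min (126 unadjusted). Whether the numbers mark pairs was not settled. Same-numbered 45 and 90 min arrays had deviations correlated at 0.0871, 0.0394 and 0.15, each small but the highest for its 45 min array. For 90 min array 2 the highest was 0.0693, with 45 min array 1. Since 90 min arrays 1 and 2 were nearly copies (r = 0.995), the check cannot tell their numbers apart. Deviations of the overexpression arrays did not follow the numbers.

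The overlap of features higher at 45 and 90 min, 175, became 49 with a 2-fold minimum, 11 with a dye coefficient and 0 with slides averaged, and that of lower features, 109, became 25, 2 and 0. The overlap of rises at 90 min and on overexpression, 4, became 1 with a dye coefficient and 1 with slides averaged, and that of falls, 2, became 1 with a 2-fold minimum and 0 with each of the other settings.

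Among the tRNA and plasmid-named groups, 1 of 16 results changed: the plasmid-named group at 45 min passed with fry (adjusted p = 0.0196) and not with camera. The other settings kept each count within 1.5 times. Aquantile moves no ratio and so tests nothing. No result changed direction past its threshold. Among values of named features under alternatives, 302 kept their side of the threshold and 118 did not pass, and of values on single mutant arrays 102 moved by less than the spread of their probes and 30 by more. The counts on the mutant arrays, 30 and 180, stayed within 1.5 times. The alternatives for the 20 gene lists were not run, since 0 of their features were measured, and slide as a fixed block was not run for ratios against 0, where it takes up the group means. Signal limits the dimmest channels: 69.4% of spots were well above background in Cy5 of 45 min array 2 and 88.4% in Cy3 of overexpression array 1.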

Other observations

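In this part, the tests of the gene carried on the plasmid, of opposite movement on overexpression and mutation, of slide or culture, and the sign patterns were chosen only after the result was seen, as were the tRNA and plasmid-named features and the runs led by Bbr_1310 and Bbr_1879.

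Of 20 tRNA features, 1 rose at 45 min, tRNA-Met at 0.78 on the log2 scale (limma adjusted p = 0.0406), and 2 rose at 90 min, tRNA-Arg at 0.27 (adjusted p = 0.028) and tRNA-Trp at 0.35 (adjusted p = 0.0197), each higher on 3 of 3 arrays. None of the 3 passed when limma's p-values were adjusted over the list alone, or with the arrays of 1 slide averaged (0.74 for tRNA-Met, adjusted p = 0.236, and at 90 min 0.28 for tRNA-Arg and 0.38 for tRNA-Trp, adjusted p = 0.28 and 0.177). As a group they did not move past the threshold against other features, with camera adjusted p = 0.573 at 45 min and 0.785 at 90 min (adjusted p = 0.94 with an estimated correlation at both times). Among the 10 features named after plasmids that were tested, pB21a-orf5 rose by 1.47 at 45 min (adjusted p = 0.000392) and 1.03 at 90 min (adjusted p = 0.000253), higher on all 6 arrays, and stood at -0.36 on overexpression (adjusted p = 0.19). With the arrays of 1 slide averaged it stood at 1.42 at 45 min, where it did not pass (adjusted p = 0.0745), and at 1.05 at 90 min (adjusted p = 0.0281). With the mean of its probes it stood at 0.60 at 90 min, so its probes did not move alike. The other plasmid-named features were dimmer, with mean log2 signals of 6.1 to 7.0 against 8.11, and none of them passed at either time. Results for the group may therefore rest on pB21a-orf5. The group had camera adjusted p = 0.573 and 0.886 (0.94 with an estimated correlation), and fry, which asks only whether the group's features move on balance, gave an adjusted p of 0.0196 at 45 min and 0.36 at 90 min.

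A run of 5 consecutive tags led by Bbr_1310 rose at 90 min with a median log2 ratio of 1.73, and stood at 0.97 on overexpression without passing there, at -0.37 on the mutant array starved for 90 min, and at -0.82 and -1.16 for mutant over wild type at 45 and 90 min. A run of 3 tags led by Bbr_1879 had a median of 1.42 at 90 min in the wild type, and 3.26 and 3.17 for mutant over wild type, so it was higher in the starved mutant than in the starved wild type. The run of 9 tags with Bbr_0327, which rose under starvation, stood at a median of -0.68 on overexpression.

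Overexpression arrays 2 and 3 showed rises that array 1 did not: 62 features were at least 2-fold higher on both, with medians of 1.58 and 1.48, and 2 of them also on array 1, where the median was 0.01. Dim signal on array 1 is argued against by the 27 of these features that were bright there, with a median of 0.0778 on array 1 against 1.63 on the others. A dye effect common to all arrays is argued against by the design, since array 1 had the same dyes and would show it too. The 90 min arrays with exchanged dyes put it at a median of 0.0186 for these features. That estimate comes from a slide with more even channel signals, so it does not test a dye effect particular to the slide of arrays 2 and 3. In Cy5, the reference dye here, 190 and 166 spots were saturated on arrays 2 and 3 and 0 on array 1. A saturated reference reads too low and raises a ratio, and whether this touched the 62 features was not tested. A slide effect and a difference between cultures cannot be told apart, since array 1 lay on another slide (r = 0.392 with array 3). The 62 features had a median of 0.67 for mutant over wild type at 90 min.

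One hypothesis is that Bbr_1683, the feature with the largest rise on overexpression, is the gene carried on the plasmid. The smallest gap between it and the next feature over the 3 arrays was 3.57 on the log2 scale. The feature was picked for its rise, and a target with a very strong response would show the same, so this gap does not test the hypothesis, which stays open. On the mutant arrays Bbr_1683 had log2 ratios of -0.02, 0.20 and 0.08.

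Another hypothesis was that overexpression and loss of phoP move features in opposite directions. Of the 6 correlations across features between an overexpression array and an array of mutant over wild type, 2 were below 0, both with overexpression array 1 (-0.316 and -0.298), and the highest of the others, all with arrays 2 and 3, was 0.0955. Arrays 2 and 3 share 1 slide and the 2 mutant arrays share another, so the 6 values amount to 2 overexpression slides that differ, and the hypothesis stays open.

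For ratios tested against 0 the arrays' signs were turned in every way, which gives 4 sign patterns for 3 arrays, too few for a share under 0.05. At 45 min the real signs gave 353 features and the highest other pattern 25, at 90 min 955 and 19, and on overexpression 12 and 0, and in each comparison only the real pattern, 1 of the 4, gave that many. Arrays of a group correlated above 0, so turning 1 of them moves the mean towards 0 and widens the spread. A bias shared by the arrays would give the same order, so these counts do not tell what caused the changes.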
